A study of Homo sapiens with 9 samples.

How the data were processed

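Gene expression was measured in HepG2, an established human liver cancer cell line with many hepatocyte features. Cells were left untreated or were given recombinant SPARC at 200 or 800 ng/ml, and RNA was collected after 24 h. SPARC is a secreted matricellular glycoprotein that binds collagen and modulates the contact of cells with their matrix. Each of the 3 groups held 3 arrays, 9 in all. Total RNA was labelled with biotin and hybridised to a 1-colour array, per the labels. The labels' extraction protocol mentions the untreated cells and the 800 ng/ml dose, whereas the sample labels and the design text give both doses. No label says whether the replicates of a group were separate cultures, so every p-value measures only the spread between these samples, which may be technical.

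The authors deposited a single table with 1 log2 value per transcript cluster and array. The submitters' processing notes name R 3.0. The normalization, the background correction and any filter are not given in the sources used here. That the scale is log2 was inferred from the range of the values, since no label states it. The values were not centred per gene. The table carries no detection calls or background signals, so no statement can be made on whether a gene lay above background, and low signals are reported only as signals. If the arrays were normalized together before deposit, which the sources used here do not say, differences in overall signal between arrays would have been reduced.

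The table held 21448 transcript clusters. The platform annotation gave 1 gene symbol to 17709 of them, several to 0 and none to 3739. The gene names were set against RefSeq names of assembly GRCh38.p14 through Entrez identifiers, which changed 0 symbols, and no coordinates were used. Where a gene had more than 1 cluster, the cluster with the highest mean over the 9 arrays was kept, which left 17687 genes. Histone and metallothionein genes have near-identical copies, and their probes can bind transcripts of more than 1 member, so values of single members are uncertain. Identical values were found in 0 pairs of arrays.

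The 3 groups were fitted together with limma 3.58.1 in R 4.3.3, with lmFit and eBayes at the default prior, on the values as deposited. A gene was called changed at a Benjamini-Hochberg adjusted p under 0.05 over all genes. Gene lists were tested with camera at a preset correlation between genes of 0.01, two-sided, with adjustment over the 34 lists of a comparison. The lists held 675 different genes, of which 600 were measured. Each list was also counted member by member, with the adjustment over all genes and over the list alone. The adjustment over a list alone does not correct for the number of lists. The lists, the design and the rule for named genes were set before the data were examined. The rule named the 10 genes with the largest rise and the 10 with the largest fall among called genes without overlap between groups. With under 10 such genes it named the 10 with the smallest p. It added up to 4 members of each called list, SPARC, and the HepG2 markers ALB, AFP and APOA1. Genes named outside this rule were chosen after their values were seen. They are the transcripts that set 800 ng/ml replicates 2 and 3 apart and the list members that passed over a list alone. Intervals are 95% intervals from the moderated fit.

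The correlation of the fold changes of the 2 doses was set beside 100 simulations of unchanged groups, because both doses share the untreated arrays. The procedure was tested on simulated data built from the signals and the spread of the real arrays, with 200 genes changed at 800 ng/ml and with the deviations of untreated replicate 2 shuffled among genes of similar signal. For 800 ng/ml against untreated with all 9 arrays and 17687 genes, it recovered 0% of the genes changed 1.5-fold, 20.9% of those changed 2-fold and 81.8% of those changed 4-fold. Without untreated replicate 2 it recovered 9.0%, 74.6% and 98.5%. These figures come from 1 simulated data set. To see how often lists are called with no effect, 20 further data sets without changed genes were simulated in the same way after the data were seen. The simulations draw genes independently, and the number of arrays limits the precision of every value.

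Alternatives set before the data were examined were quantile normalization, median centring and leaving out the dimmest 25% or 50% of genes. They also covered the mean of all clusters of a gene, a trended robust prior, fits of only the 6 arrays compared, the replicate number as a block, array weights and a minimum of 1.5-fold. For lists they were an estimated correlation and ranks. The estimated correlation was not tried on the simulated data, so a call lost with it does not show that the list was unchanged. Each array was also left out in turn. An offset before taking logarithms was planned only for linear values and was not run. After the data were seen, further fits were added. These combined leaving out untreated replicate 2 with other settings, left out untreated replicate 2 and 200 ng/ml replicate 1 together or 800 ng/ml replicates 2 and 3 together, or adjusted for the deviation of untreated replicate 2. The estimated correlation was also combined with the fits of 6 arrays and with leaving out 800 ng/ml replicate 1. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

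For the closing section, 12 lists of cell type markers were written after genes that stood apart in 800 ng/ml replicates 2 and 3 had been inspected. The astrocyte list contained GFAP and SLC4A4, and the list for oligodendrocyte precursors contained BCAN and PTPRZ1, whose high signals in those arrays had already been seen. Values of other members had appeared in earlier output for other reasons, namely MAG and MAL of the mature oligodendrocyte list, COL1A1 of the fibroblast list and ALB, AFP and APOA1 of the hepatocyte list. The lists were therefore also evaluated without all of these members.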

Results

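The transcriptome of HepG2 cells was profiled 24 h after exposure to recombinant SPARC, to ask how this matricellular protein alters gene expression in a liver cancer cell line. The 9 arrays comprised 3 untreated samples, 3 samples at 200 ng/ml and 3 at 800 ng/ml. The median log2 signal was 5.44, 5.55 and 5.41 in untreated replicates 1, 2 and 3. It was 5.47, 5.45 and 5.46 in the 200 ng/ml replicates and 5.41, 5.43 and 5.41 in the 800 ng/ml replicates.

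Untreated replicate 2 stood apart from the other arrays. Its Pearson correlation across transcript clusters was between 0.891 and 0.920 with every other array, whereas the other 8 arrays correlated with each other at 0.979 to 0.991. The SD of its signals was 1.67, against 1.914 to 2.003 in the other 8 arrays. Relative to the mean of untreated replicates 1 and 3, the median deviation of its genes was 0.41, 0.56, −0.53 and −0.83 in 4 equal bins of genes from the dimmest to the brightest. Dim genes were thus higher and bright genes lower in this array. It is 1 of the 3 untreated samples on which both comparisons with untreated cells rest, and the results are therefore also given without it, a setting planned as part of leaving out each array in turn.

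**Figure D1:**
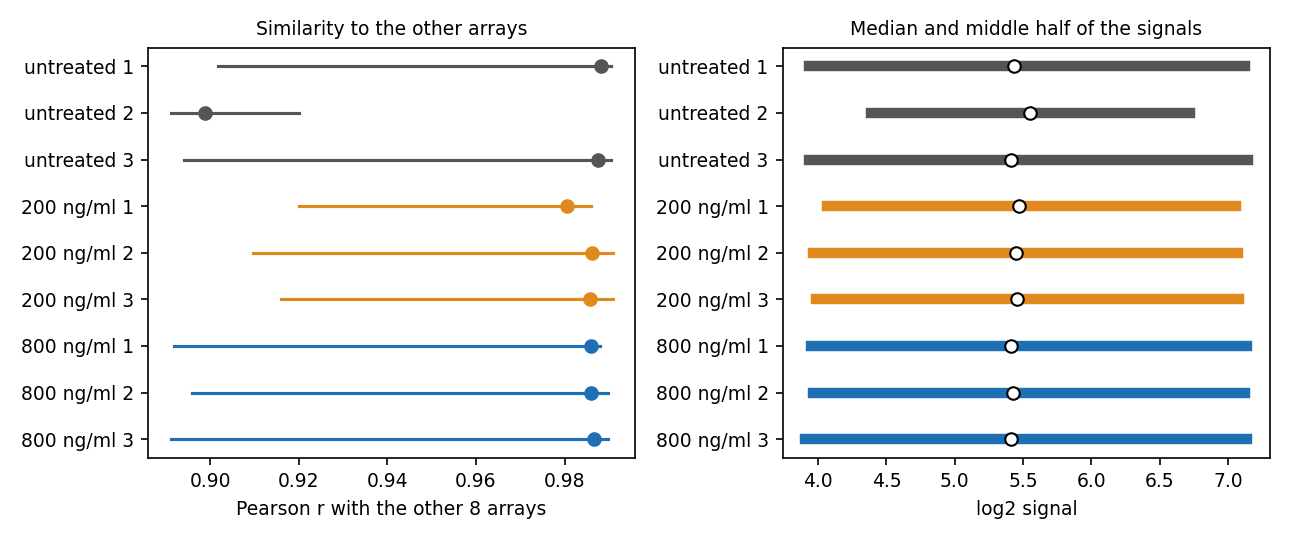
Left, Pearson correlation of each array with the other 8 arrays (line, lowest to highest; point, median); right, median (circle) and interquartile range (bar) of the log2 signals of each array. Untreated replicate 2 has correlations of 0.891 to 0.920 with every other array and the narrowest interquartile range of signals.

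Markers of the hepatocyte identity of the line were measured in all 3 groups. ALB, the main plasma protein of hepatocytes, had a log2 signal of 12.23 ± 0.08 (SD, n = 3) in untreated cells, 12.32 ± 0.04 at 200 ng/ml and 12.38 ± 0.07 at 800 ng/ml. AFP, the fetal counterpart of albumin, had 8.71 ± 0.48, 9.09 ± 0.12 and 9.11 ± 0.07 in the same order. APOA1, the main protein of high-density lipoprotein, had 10.14 ± 0.21, 10.33 ± 0.13 and 10.27 ± 0.06. None of these genes passed the test in any comparison. The list of hepatocyte secreted proteins and regulators had a mean log2 difference from untreated of 0.13 at both doses, with 21 and 22 of 27 members higher, and was not called (camera, adjusted p = 0.0920 and 0.135). It was called at 200 ng/ml without untreated replicate 1 (mean 0.21, adjusted p = 0.0263) and without 200 ng/ml replicate 1 (mean 0.15, adjusted p = 0.0439). Both leave-out fits used the preset correlation only, and with all arrays an estimated correlation called 0 lists at 200 ng/ml. Untreated replicate 2 was at −0.43 on this list relative to the mean of the other 8 arrays, and leaving it out gave means of −0.03 and −0.02 (adjusted p = 0.740 and 0.993).

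The transcript of SPARC itself (TC0500012519.hg.1) had a log2 signal of 4.16 ± 0.11 (SD, n = 3) in untreated cells and 3.71 ± 0.20 at 200 ng/ml. At 800 ng/ml it had 5.81 ± 1.43, because the 3 arrays disagreed, with 4.18 in replicate 1, 6.79 in replicate 2 and 6.48 in replicate 3. The log2 difference from untreated cells was 1.66 with a 95% interval of 0.51 to 2.81 (limma, adjusted p = 0.659), so the test was not passed. Other transcripts had the same distribution, and they were chosen after their values were seen. NTRK2, a neurotrophin receptor, had 3.63, 6.96 and 7.28 in 800 ng/ml replicates 1, 2 and 3. GFAP, an intermediate filament protein of astrocytes, had 4.54, 7.88 and 7.75. SPARCL1, a relative of SPARC, had 3.81, 6.48 and 6.39.

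**Figure D2:**
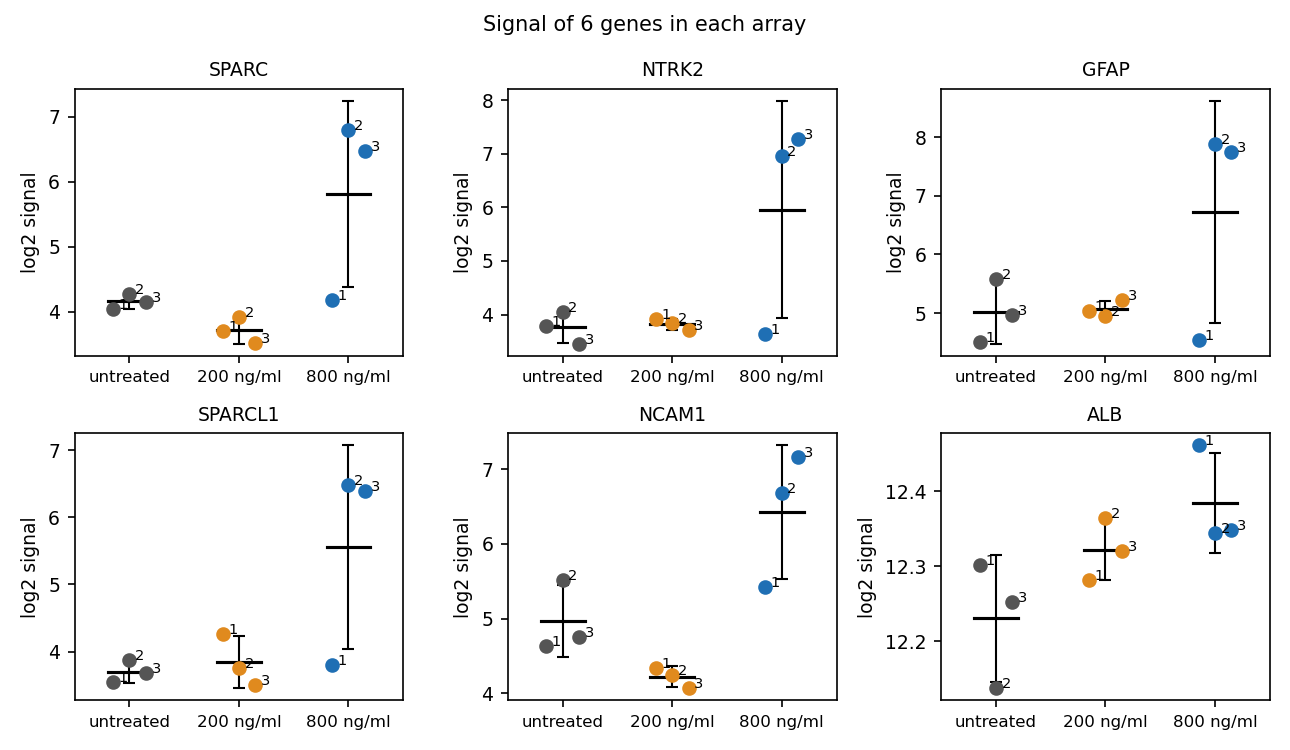
Log2 signal of SPARC, NTRK2, GFAP, SPARCL1, NCAM1 and ALB in each array; points are arrays with their replicate number, horizontal bars are group means and error bars are SDs (n = 3). SPARC, NTRK2, GFAP and SPARCL1 are high in 800 ng/ml replicates 2 and 3 and not in replicate 1, and the axes do not start at 0.

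In cells given 200 ng/ml SPARC, 0 of 17687 genes passed the test against untreated cells (limma, smallest adjusted p = 0.966). At an unadjusted p under 0.05 there were 315 genes, where 884 are expected by chance alone. The 10 genes with the smallest p did not pass either. They included FAXC, with a log2 difference of −0.85 ± 0.22 (SE), and GPC4, a cell surface proteoglycan, with −0.87 ± 0.26. ADIPOR2, a receptor for adiponectin, had 0.88 ± 0.23, and DCXR, an enzyme of xylulose metabolism, had 0.72 ± 0.21. ITGA5, the alpha subunit of the fibronectin receptor, had −0.63 ± 0.19, AMPD3 had −0.74 ± 0.21 and INPPL1 had 0.62 ± 0.18. VIM-AS1, TSC22D4 and AZI2 had −0.85 ± 0.25, −0.68 ± 0.21 and 0.71 ± 0.21.

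Camera called 2 of the 34 gene lists at 200 ng/ml. Histone genes, which supply nucleosome proteins, had a mean log2 difference of 0.32 with 12 of 13 members higher (adjusted p = 9.18e-05). H1-4, H4C3, H3C10 and H2BC21 had ratios of 1.36, 1.28, 1.59 and 1.40, none of which passed. Cell cycle genes had a mean of 0.21 with 25 of 28 members higher (adjusted p = 0.0083). The mitotic genes CDC20, UBE2C and MKI67 had ratios of 1.45, 1.54 and 1.31, and E2F2, a transcription factor of the G1 to S transition, had 1.42, again none past the test. With all 9 arrays no member of any list passed when adjusted over all genes or when adjusted over the list alone. Both calls were lost with an estimated correlation (adjusted p = 0.809). Markers of endothelium, fibroblasts and blood or Kupffer cells were lower at 200 ng/ml, with no call. Relative to the mean of the 8 arrays other than untreated replicate 2, they were at 0.05, 0.05 and 0.09. Untreated cells were at 0.24, 0.20 and 0.23, with untreated replicate 2 at 0.80, 0.69 and 0.77. Cholangiocyte markers were at 0.02 against 0.004 in untreated cells.

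Without untreated replicate 2 no list was called at 200 ng/ml, the cell cycle mean turned to −0.09 and the histone mean was 0.11 (adjusted p = 0.222). In that fit KDM3A, a hypoxia-induced demethylase, with −0.74 ± 0.15 (SE), the chemokine CCL20 with −0.60 ± 0.11, ICAM1 with −0.50 ± 0.13 and AMOTL1 with 0.52 ± 0.12 passed when adjusted over the list alone, and 0 genes over all genes (smallest adjusted p = 0.309). The number of genes with an unadjusted p under 0.05 was then 2002, above the 884 expected. On the first principal component of the 9 arrays the 200 ng/ml arrays lay toward untreated replicate 2, at 5.79, −8.48 and −3.87 against 99.0. Untreated replicates 1 and 3 were at −15.3 and −20.1. A gradient of array or RNA quality shared with untreated replicate 2 may thus be part of this excess, which was not tested. In 20 simulations of unchanged groups, with the deviations of untreated replicate 2 shuffled among genes of similar signal, camera called a median of 5 lists, between 1 and 12. The shuffling removes deviations shared by the members of a list, so this range need not hold for the real deviations.

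In cells given 800 ng/ml SPARC, 0 of 17687 genes passed against untreated cells (limma, smallest adjusted p = 0.659), and 737 had an unadjusted p under 0.05 against 884 expected. The smallest p belonged to AMPD3, an AMP deaminase, with a log2 difference of −1.11 ± 0.21 (SE) and an interval of −1.56 to −0.66. GPC4 had −1.03 ± 0.26, CRYBG2 −1.24 ± 0.32 and FOXO6, a forkhead transcription factor, −1.02 ± 0.25. INPP5E, a phosphoinositide phosphatase of the primary cilium, had −0.77 ± 0.18, PPP1R3D −0.97 ± 0.23 and DNAAF8 −0.87 ± 0.21. DPP6, ADIPOR2 and TMEM234 had 0.90 ± 0.20, 0.98 ± 0.23 and 1.12 ± 0.28. AMPD3, ADIPOR2 and GPC4 were also among the 10 smallest p-values at 200 ng/ml, where the same untreated arrays were used.

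Camera called 7 of the 34 lists at 800 ng/ml with the preset correlation and 0 with an estimated correlation. Cell cycle genes had a mean log2 difference of 0.26 with 26 of 28 members higher, the mitochondrial respiratory chain 0.24 with 21 of 23 and the spliceosome 0.25 with 19 of 19 (adjusted p = 0.0157 for each). KIF11, CCNB1 and CENPF of the cell cycle list had ratios of 1.59, 1.40 and 1.43. COX5B and ATP5PO of the respiratory chain had 1.49 and 1.36, and SRSF7 and HNRNPA2B1 of the spliceosome had 1.495 and 1.42. Fatty acid oxidation had a mean of 0.25 with 18 of 20 members higher (adjusted p = 0.0245), with ACADM and ACAA2, enzymes of mitochondrial beta-oxidation, at 1.42 and 1.35. The heat shock list had 0.28 with 15 of 16 higher (adjusted p = 0.0245), led by HSPB8 at 1.67 and CRYAB at 2.44. CRYAB, also a glial chaperone, had 3.77 in 800 ng/ml replicate 1 and 5.80 and 6.33 in replicates 2 and 3.

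The oxidative stress list had a mean of 0.24 with 17 of 18 members higher (adjusted p = 0.0451), including GCLC, an enzyme of glutathione synthesis, at a ratio of 1.48. Markers of blood and Kupffer cells had a mean of −0.29 with 11 of 13 lower (adjusted p = 0.0332), including CD3E at 0.567 and MARCO at 0.662. Markers of fibroblasts and of endothelium were lower too, with means of −0.21 (9 of 12 lower, adjusted p = 0.120) and −0.27 (10 of 10 lower, adjusted p = 0.0693). In untreated replicate 2 these lists were high, since their median deviations from untreated replicates 1 and 3 were 0.992 for blood and Kupffer cells, 0.928 for fibroblasts and 0.859 for endothelium. Without that array the means at 800 ng/ml were −0.02, 0.04 and 0.01 in the same order. With all 9 arrays no member passed over all genes or when adjusted over the list alone, and all 7 calls were lost with an estimated correlation (adjusted p = 0.732). Whether that setting can call a list that does change was not simulated.

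When untreated replicate 2 was left out, 0 lists were called at 800 ng/ml. Of the lists called with all 9 arrays, the heat shock mean was then 0.11 with 9 of 16 members higher (adjusted p = 0.993) and the fatty acid oxidation mean 0.05 with 14 of 20 higher (adjusted p = 0.760). The means of the cell cycle, the respiratory chain, the spliceosome and oxidative stress were −0.04, −0.02, 0.03 and 0.01. Genes with an unadjusted p under 0.05 numbered 948, and 0 passed (smallest adjusted p = 0.861). ITGA5 with −0.60 ± 0.15 (SE) then passed when adjusted over the mesenchymal transition list alone, but not over the integrin list, which also holds it. AMOTL1 with 0.56 ± 0.12 passed over the list of Hippo pathway targets alone. In the simulations of unchanged groups, with the shuffled deviations of untreated replicate 2, a median of 6 lists was called, between 0 and 11. After quantile normalization of the real arrays 0 lists were called.

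Among the lists closest to the known roles of SPARC, extracellular matrix genes had a mean log2 difference of −0.02 at 200 ng/ml (adjusted p = 0.758) and 0.20 at 800 ng/ml (adjusted p = 0.220). Integrins and adhesion receptors had 0.04 and 0.09 (adjusted p = 0.826 and 0.584), and genes of mesenchymal transition had −0.05 and −0.05 (adjusted p = 0.454 and 0.459). TGF-beta targets had 0.19 and 0.15 (adjusted p = 0.0663 and 0.1502). None of these lists was called with all 9 arrays. The TGF-beta means without untreated replicate 2 turned to −0.02 and −0.06 and those of integrins to −0.05 and −0.01. Extracellular matrix genes had −0.003 and 0.217 and mesenchymal transition −0.011 and −0.004 in that fit, with no call. Leaving out untreated replicate 1 or 3 instead gave a call for TGF-beta targets at 200 ng/ml (means 0.29 and 0.29, adjusted p = 0.0257 and 0.0256). These leave-out fits used the preset correlation only, and with all 9 arrays an estimated correlation called 0 lists at 200 ng/ml. Leaving out 800 ng/ml replicate 1 gave a call for extracellular matrix genes at 800 ng/ml against untreated (mean 0.28, adjusted p = 0.0486) and against 200 ng/ml (mean 0.30, adjusted p = 0.0226). Both matrix calls were lost with an estimated correlation (adjusted p = 0.732 and adjusted p = 0.454). SPARC and SPARCL1 are members of this list and had 2.48 and 2.73 against untreated without 800 ng/ml replicate 1. These genes thus supply most of its mean of 0.28 over 22 measured members. Without untreated replicate 2 SPARC had 1.71 at 800 ng/ml.

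The comparison of 800 with 200 ng/ml asks whether the dose matters, and its fold changes do not involve the untreated arrays. Again 0 of 17687 genes passed (limma, smallest adjusted p = 0.999), with 427 genes at an unadjusted p under 0.05 against 884 expected. NCAM1, a neural cell adhesion molecule, had the smallest p, with a log2 difference of 2.203 ± 0.389 (SE) and an interval of 1.35 to 3.06. Its signals were 5.42, 6.68 and 7.16 in 800 ng/ml replicates 1, 2 and 3. SPARC had 2.10 ± 0.52, GPM6A, a neuronal membrane glycoprotein, 1.64 ± 0.45, and OGFRL1 1.44 ± 0.38, and each of these was high in replicates 2 and 3 only. SPARC passed when adjusted over the list alone, among the extracellular matrix genes (adjusted p = 0.0425), and with all 9 arrays no other list member did so. Without untreated replicate 2, COL1A2 with −0.62 ± 0.14, PDK1 with 0.38 ± 0.10, ANKRD37 with −0.65 ± 0.14, KDM3A with 0.66 ± 0.13, SLC1A2 with 0.80 ± 0.17 and ITGAM with −0.49 ± 0.125 also passed over their lists alone. FOXF1, a forkhead transcription factor, had −0.82 ± 0.19, AFAP1L2 −0.77 ± 0.19, LINC00482 −0.76 ± 0.20, LOC440895 −0.88 ± 0.23 and PABPC4L −0.71 ± 0.19. S100A8, a calcium-binding protein of myeloid cells, had 0.65 ± 0.17.

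No list was called between the doses. Histone genes had a mean of −0.18 with 13 of 13 members lower at 800 ng/ml, and fatty acid oxidation had 0.16 with 16 of 20 higher (adjusted p = 0.0777 for both). Replicate 1 carried much of both differences. Relative to the mean of the 8 arrays other than untreated replicate 2, the histone list was at −0.23, −0.03 and 0.01 in 800 ng/ml replicates 1, 2 and 3, and fatty acid oxidation at 0.18, 0.02 and 0.02. Leaving out replicate 1 gave means of −0.10 and 0.11 (adjusted p = 0.523 and adjusted p = 0.343). Without untreated replicate 2, which then no longer widened the shared estimate of spread, both lists passed (adjusted p = 0.0226), and neither did with an estimated correlation (adjusted p = 0.765). In that fit the number of genes with an unadjusted p under 0.05 was 2698, and 0 genes passed (smallest adjusted p = 0.154).

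The arrays of the 2 doses did not overlap for 21.9% of genes, where chance gives 10% on average over all splits. The corresponding shares were 6.98% for 200 ng/ml and 11.2% for 800 ng/ml against untreated. Genes vary together across arrays, so a share away from 10% does not by itself show an effect of SPARC. The median gene had a 95% interval that reached 1.45-fold either way, and 1.24-fold for the dose comparison without untreated replicate 2. Leaving out 800 ng/ml replicate 1 gave 12 called genes against untreated and 15 against 200 ng/ml, with NTRK2, ADCYAP1R1, SPARC and SPARCL1 leading the first set. Array weights gave 1971, 732 and 6 genes in the order of the comparisons above. In that fit untreated replicate 1 received a weight of 10.7 against 0.0399 for replicate 2, and the estimation of the weights gave a convergence warning. Whether the counts depend on untreated replicate 1 was not tested. Without untreated replicate 2, array weights gave 0 genes in each comparison.

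**Figure D3:**
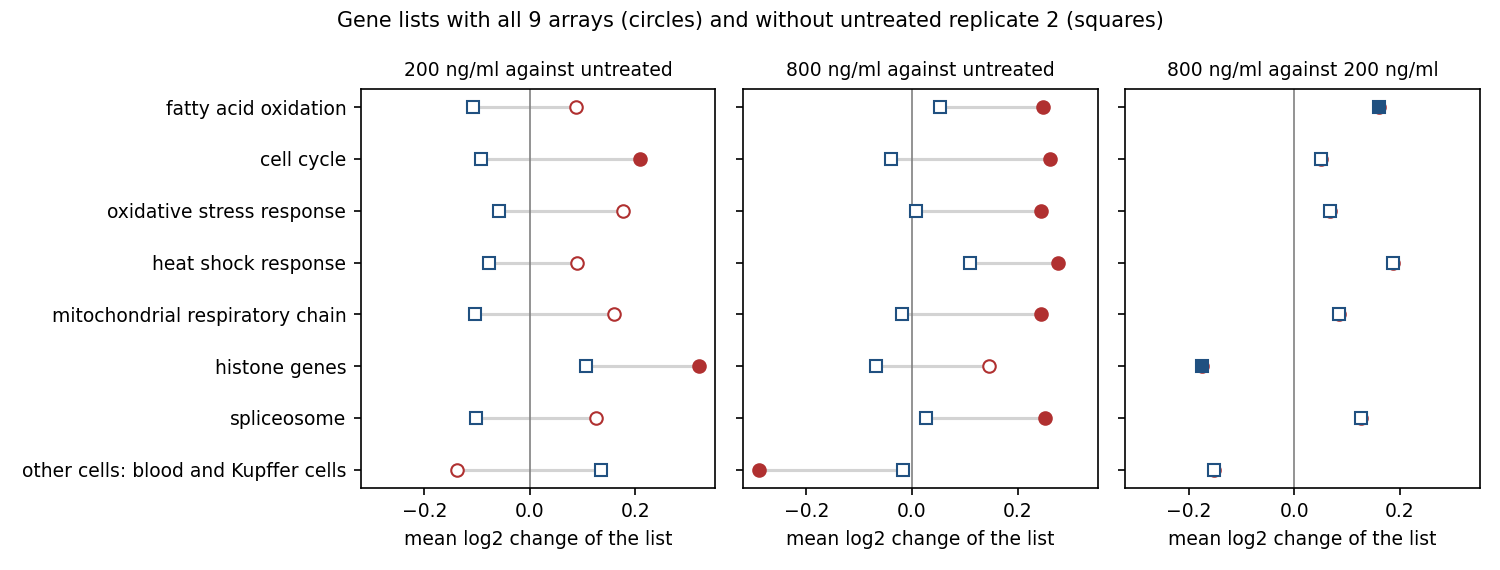
Mean log2 change of the 8 gene lists called in any comparison, with all 9 arrays (circles) and without untreated replicate 2 (squares); filled symbols passed an adjusted p under 0.05 (camera, preset correlation). Against untreated cells the cell cycle mean changes from 0.21 to −0.09 at 200 ng/ml and from 0.26 to −0.04 at 800 ng/ml, whereas the means between the doses do not involve that array and coincide.

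The fold changes of the 2 doses against untreated cells correlated across genes at r = 0.696, and genes are not independent replicates. Simulated unchanged groups with the same controls gave r = 0.885. The covariance was 0.0611 against a simulated 0.0953. On the other 8 arrays, untreated replicate 2 left out, the correlation was 0.378 against a simulated 0.600, and the covariance was 0.0181 against 0.0186. The correlation between the doses was thus not above the simulated one, and the covariance without untreated replicate 2 differed from the simulated one by −0.00048. Both correlations lay below the simulated ranges, 0.881 to 0.889 with all 9 arrays and 0.581 to 0.618 without untreated replicate 2. The simulated groups therefore do not describe these arrays, and the comparison cannot decide on a response shared by the doses.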

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

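Fits that combine 2 changes, the 6-array list fits, the pairs of arrays left out together and the adjusted 6-array fit were chosen after the data were seen. The cause of the shifts listed here was not tested unless a value shows it. Gene counts were 0 in all 3 comparisons at the main setting. Of 57 counts under settings fixed beforehand 52 were 0, and of 22 added counts 17 were 0. Array weights gave 1971, 732 and 6 genes. Leaving out each array gave 0 genes at 200 ng/ml, 0 to 12 at 800 ng/ml and 0 to 15 between doses, the upper values without 800 ng/ml replicate 1. With a trended robust prior and without untreated replicate 2 there were 28 genes at 200 ng/ml and 13 between doses. Without 200 ng/ml replicate 1 as well there were 68 and 20, and with only the arrays of the 2 groups there were 2 at 200 ng/ml. The default prior gave 0 in each of these.

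Lists called were 2, 7 and 0 in the main setting. Quantile normalization gave 1, 0 and 1, and leaving out the dimmest 25% gave 1 at 200 ng/ml and 0 at 800 ng/ml. An estimated correlation gave 0 and 0 against untreated, with or without untreated replicate 2, without 800 ng/ml replicate 1, or on 6 arrays. Leaving out each array gave 0 to 14 lists at 200 ng/ml, 0 to 12 at 800 ng/ml and 0 to 2 between doses, where the value of 0 against untreated came without untreated replicate 2. Without 800 ng/ml replicates 2 and 3 there were 3 lists at 800 ng/ml and 3 between doses, but this fit holds 1 array at 800 ng/ml and takes the spread from the other groups, so these calls describe that array alone. Between doses the 6-array fit and ranks gave 2 each, and the adjusted fit gave 1. The cell cycle mean reversed without untreated replicate 2, to −0.0921 at 200 ng/ml and −0.0408 at 800 ng/ml, with either correlation, and was 0.366 and 0.417 without untreated replicate 3.

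The correlation of the doses was 0.722 after quantile normalization and 0.705 without the dimmest 25%, and 0.378 to 0.862 with each array left out, lowest without untreated replicate 2. A shift counted as a move above the SD of the simulated r, 0.00157. The replicate numbers showed no pairing of the samples, since 1 of 9 same-number pairs had deviations correlated above 0.1 and 1 array correlated best with its own number. Pairs with untreated arrays could hardly show one, because untreated replicates 1 and 3 mirrored replicate 2. Untreated replicates 1, 3 and 2 correlated with 200 ng/ml replicate 1 at −0.25, −0.24 and 0.27. Same-number pairs of the 2 doses had 0.0001, −0.046 and 0.034. The replicate block gave 0, 0 and 0 genes and 2, 7 and 0 lists. Of 2022 values of named genes under alternatives, 32 had the opposite sign with no call in either and 39 passed the threshold. Without detection calls, the limit set by signal over background is not known.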

Other observations

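Of the tests in this part, those on the neural transcripts and on the quality gradient were chosen after the result was seen, and those on signal compression and on other splits of the arrays were written before.

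Some transcripts were higher in 800 ng/ml replicates 2 and 3 than in replicate 1. In total 23 genes lay more than 1 log2 unit above the 6 remaining arrays in both, untreated replicate 2 not considered, whereas the other 27 pairs among the 8 arrays gave at most 0 such genes. They included ADCYAP1R1, a neuropeptide receptor, at 6.29 and 6.22 in these arrays and 3.39 in 800 ng/ml replicate 1. PMP2, a myelin protein, had 5.83 and 5.90 against 3.19, and SOX2, a transcription factor of neural progenitors, 5.84 and 6.06 against 4.07. SLC1A3, an astrocyte glutamate transporter, had 6.72 and 6.75 against 5.05, and BCAN, a brain proteoglycan, 5.89 and 6.13 against 4.57. The set also held NTRK2, GFAP, SPARC, SPARCL1, NCAM1, GPM6A, CRYAB, TSPAN7, GABBR1, GPM6B, ATP1B2 and PPP2R2B. NCAM1 was also raised in 800 ng/ml replicate 1, at 5.42 against 4.63 and 4.76 in untreated replicates 1 and 3. It had 4.34, 4.24 and 4.07 at 200 ng/ml and 5.52 in untreated replicate 2. Its remaining members were SRI, RAB31, TCF4, SCD5, OGFRL1 and RFTN2. Untreated replicate 2 had 6.43 for SLC1A3, 5.27 for BCAN, 6.85 for GABBR1, 6.02 for TCF4, 6.18 for GPM6B and 4.25 for PPP2R2B. With that array counted, these genes would have missed the gap of 1, and the other members of the set would have kept it. No fixed list or enrichment test gives the set a theme.

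RNA of glial cells in these libraries is a candidate explanation, and the tests leave it open. The criterion written for it was a median astrocyte difference above 0.3 against 800 ng/ml replicate 1 and the 200 ng/ml arrays. The median was 0.2137 over 17 markers, the highest of the 12 lists but short of that criterion. Without the members seen beforehand it was 0.10 over 15 markers, and mature oligodendrocytes had 0.13 over 9 without MAG and MAL and 0.06 over all 11, so the rank depends on which members are kept. Of the 17 astrocyte markers 7 lay above the 6 other arrays in both, and 5 of the 15 not seen before, against 4.03% of all genes. The counts were 3 of 11 for oligodendrocyte precursors, 2 of 15 for neurons and 2 of 13 for fibroblasts. Mature oligodendrocytes, microglia and hepatocytes had 1 each, and endothelium, skeletal muscle, kidney, lung and lymphocytes had 0. The astrocyte count decides nothing, because that list was written after neural and glial genes had been seen in these arrays. Against untreated replicates 1 and 3 the astrocyte median was 0.14, below oligodendrocyte precursors (0.36), microglia (0.17) and neurons (0.17).

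A response to 800 ng/ml SPARC also stays open. Of the 12 genes called without replicate 1, 1 lay above every untreated and 200 ng/ml array in replicate 1, but these genes were picked by leaving that array out, so the count decides nothing. Replacement of HepG2 by another sample is argued against by the hepatocyte markers, whose median differed from replicate 1 by 0.0692, although ALB, AFP and APOA1 had been seen before.

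The medians of the other lists against the same arrays were 0.06 for oligodendrocyte precursors and 0.06 for mature oligodendrocytes, −0.04 for neurons and 0.03 for microglia. They were 0.05 for fibroblasts, −0.07 for endothelium, −0.14 for skeletal muscle and −0.25 for kidney epithelium. Lung epithelium had −0.09, lymphocytes −0.17 and hepatocytes 0.04. HepG2 expresses the hepatocyte markers itself.

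The difference between the doses ran along the deviation of untreated replicate 2. Across genes the log2 difference of 800 from 200 ng/ml correlated with the deviation of that array from untreated replicates 1 and 3 at −0.4544. With a smooth trend on mean signal removed from both, the correlation was −0.4218, which argues against signal compression alone. A gradient of array or RNA quality that also affects untreated replicate 2 may account for part of the dose difference, and a response to SPARC stays open. The first principal component of the 9 arrays held 66.12% of the variance and mainly set untreated replicate 2 apart. Positions along it did not follow the dose, but an axis set by that array cannot decide on a response to dose. Untreated replicates 1 and 3 were at −15.3 and −20.1, and the 800 ng/ml arrays at −19.2, −16.5 and −21.3. The 200 ng/ml arrays lay toward untreated replicate 2, at 5.79, −8.48 and −3.87 against 99.0. In a fit of only the 6 arrays of the 2 doses the histone and fatty acid oxidation lists were both called (adjusted p = 0.0292 for each, and adjusted p = 0.877 with an estimated correlation). After adjustment for the deviation, histone genes had a mean of −0.23 (adjusted p = 0.00069, and adjusted p = 0.925 with an estimated correlation). Fatty acid oxidation then had a mean of 0.10 against 0.16 before (adjusted p = 0.234).

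With 3 arrays against 3 there are 10 splits, too few for a share under 0.05. For genes, the real split gave 0 in each comparison and the highest other split 0, so all 10, 10 and 10 splits gave as many. A count of 0 throughout cannot tell the splits apart. At an unadjusted p under 0.05 the real split gave 315 genes at 200 ng/ml, 737 at 800 ng/ml and 427 between doses. The highest other split gave 2589, 776 and 181, so only between doses did the real split give the most. For lists at 200 ng/ml the real split gave 2 and the highest other 15, with 10 splits as large. At 800 ng/ml it gave 7 and the highest other 18, with 8 as large, and between doses it gave 0 and the highest other 2, with 10 as large.

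Among the 3739 clusters with no symbol in the annotation, tested separately, 0 passed in any comparison, with 114, 206 and 141 at an unadjusted p under 0.05. Without untreated replicate 2, 4 passed between the doses.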
